A study of Mus musculus with 3 samples.

How the data were processed

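The study compared total RNA of SOL muscle from KO and WT mice, extracted with Trizol and labelled with a low-input Agilent kit, per the labels' protocols, with WT in Cy3 and KO in Cy5 on each of 3 arrays. Each deposited scanner file holds the intensity of every spot in both channels, its local background, quality flags and a processed signal. The files were made with Feature Extraction 12.0.3.1 per the file headers, while the submitters' processing notes name Agilent Feature Extraction 11.5. The processed signal is background-subtracted and dye-normalised by that software, per the file headers. The deposited series matrix holds 1 log10 ratio per spot. Set against the scanner files it equalled the log10 ratio of KO over WT to within 5e-10 on arrays 1 and 2 and to within 0.0050 on array 3, where it was rounded. Its column medians were 0, 0 and 0, and it lists 28540, 29526 and 32272 non-control spots at 0. Its direction follows the dyes and it was not centred further. All 3 arrays lay on 1 slide.

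Ratios were computed from the median spot intensity, since the mean is not in the files used here, and the local background median. Background was corrected with normexp and an offset of 50 over all spots, and loess was fitted within each array with control spots and spots with an outlier flag at weight 0, using limma 3.58.1 in R 4.3.3 with files read by the data.table package (version 1.17.8). The offset is large against these arrays, whose median background was 35, 36 and 32 in the WT channel and 17 in the KO channel of each array, and it shrinks the ratios of dim probes. Spots with an outlier flag were left out, 536, 572 and 1002 on arrays 1 to 3, and 0 spots were saturated. Spots of one probe were averaged. A probe was tested if it had a value on all 3 arrays and was well above background on all 3 in at least 1 channel, which left 8391 of 55681 probes. Probes were named by matching their accession, without version, to a RefSeq table of assembly GRCm38.p6. Of 29472 probes with a RefSeq accession 28664 matched, and other probes kept the name in the file. That reference gave names and no coordinates. A gene was represented by its probe of highest average intensity, and 825 genes had more than 1 tested probe.

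The mean ratio was tested against 0 in limma with 1 value per array, moderated with eBayes, with Benjamini-Hochberg adjustment over 7424 genes or unnamed transcripts, a threshold of 0.05 and both directions. SD values are between arrays. The array pairs 1 KO with 1 WT sample. The channels of one array deviated together, with correlations across genes of 0.853, 0.858 and 0.904 on arrays 1 to 3, which the shared spots alone can give. Ratios of different arrays correlated across genes at 0.350 for arrays 1 and 2, 0.206 for arrays 1 and 3 and 0.333 for arrays 2 and 3. Gene lists, the rule for named genes and the alternatives not said below to be added were fixed before the data were examined. There were 17 lists of pathways and 9 of cell type markers, tested with camera at a preset correlation of 0.01, adjusted over 25 lists. Estimated correlation and fry were alternatives.

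The rule for named genes took 10 genes always, up to 12 per direction past the threshold with 1 sign on all arrays and a named transcript, filled to 12 by the smallest unadjusted p with an absolute log2 ratio of at least 0.58, and the 3 members of smallest p of each list that is not only summarised. The genes and lists that did not pass are given as such.

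The steps were tested on simulated arrays with the real backgrounds and with spreads scaled to the real ones (median SD 0.120 in both). Of 100 genes changed by a log2 ratio of 2, 64 were recovered, with a median fitted size of 1.20. Of 100 changed by 1, 23 were recovered, with a median fitted size of 0.55. Of the 90 calls among 7424 genes, 3 were unchanged genes. A list of 40 genes shifted by 0.3 passed with the preset correlation (adjusted p = 8.7e-11) and did not with an estimated one (adjusted p = 0.359), while 0 of 20 unshifted lists passed either. In these simulated data the genes were independent.

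Alternatives changed the background correction, offset, normalisation within and between arrays, the source of the ratio, the filter on dim probes, the handling of saturated spots and of several probes, the moderation, array weights, the thresholds, the channels as separate samples and the arrays used. Added after seeing the data were centring on the tested probes, keeping spots with an outlier flag, testing each probe and leaving Mettl21c out of its list.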

Results

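Gene expression was measured in a hindlimb muscle named SOL in the labels, read here as the soleus, of male C57BL/6 mice aged 8 weeks. Mice homozygous for a LacZ allele of Mettl21c (KO) were compared with wild-type mice (WT). Mettl21c belongs to a family of lysine methyltransferases that act on proteins such as chaperones. There were 3 biological replicates of each genotype, hybridised as 3 arrays with 2 colours, each holding 1 WT sample in Cy3 and 1 KO sample in Cy5. The dyes were never exchanged, so any preference of a probe for one dye cannot be separated from the genotype. Between 22.5% and 22.9% of the 59305 non-control spots were well above background in the KO channel, and between 20.4% and 23.6% in the WT channel. The number of arrays limits the precision of every value. The test covered 7424 genes or unnamed transcripts, of which 5776 carried a gene symbol.

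The first question was whether the targeted transcript was lower in the samples labelled KO. Mettl21c fell by 2.45 on the log2 scale (SD 0.48, n = 3 arrays, limma adjusted p = 0.0175), and its log2 ratios of KO over WT were -2.93, -1.96 and -2.46 on arrays 1 to 3. On the offset scale used here that mean is 5.47-fold lower in KO. The scanner's processed signals, which carry no offset, gave a mean log2 ratio of -6.23 (SD 0.87, n = 3). The processed WT signals were 7527, 3677 and 4486, and the processed KO signals were 200.4, 32.3 and 45.4. The KO channel was well above background on array 1 alone, where the processed signals gave a log2 ratio of -5.23, so on the other arrays the size of the ratio was not measured. The gene has 1 probe on the array, and the files do not place it relative to the deleted part. With the processed signals in the same limma fit the adjusted p was 0.0680, and over all alternatives it ran from 1.5e-07 to 0.752. The upper end came from the 6 channels fitted as separate samples, which ignores the pairing within an array.

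The second question was which other transcripts differed between KO and WT soleus. Beside Mettl21c, 2 transcripts passed an adjusted p of 0.05 in limma, both lower in KO, and 0 were higher. At an unadjusted p under 0.05 there were 997, 438 higher and 559 lower, against 371 expected by chance. Chac1, a glutathione-degrading enzyme induced by the ATF4 stress pathway, fell by 0.96 (SD 0.20, n = 3 arrays, limma adjusted p = 0.0481, and from 6.3e-04 to 1.00 over the alternatives). The other is a transcript named only by its region, chromosome 19 from 5798135 to 5800557, with the build not given. Its brightest probe fell by 0.77 (SD 0.10, n = 3, limma adjusted p = 0.0481, and from 4.0e-04 to 1.00 over the alternatives), while the other tested probe of the region stood at -0.18 (SD 0.10). An offset of 16 gave -1.18 and no background subtraction gave -1.15. The processed signals, dye-normalised by Feature Extraction with no loess fitted here, gave -2.09. The region lies outside the rule for named genes and was chosen after its values were seen. Without array 3 limma called 0 transcripts, with 1320 of 9620 tested at an unadjusted p under 0.05. Without array 1 it called 9 and without array 2 it called 16. Robust, trended moderation in limma called 41 higher and 44 lower, and array weights called 45 higher and 17 lower. The 6 channels fitted as separate samples gave 0 calls, with 236 at an unadjusted p under 0.05. That fit ignores the pairing within an array and gave the upper ends of the ranges for Chac1 and the region.

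**Figure D1:**
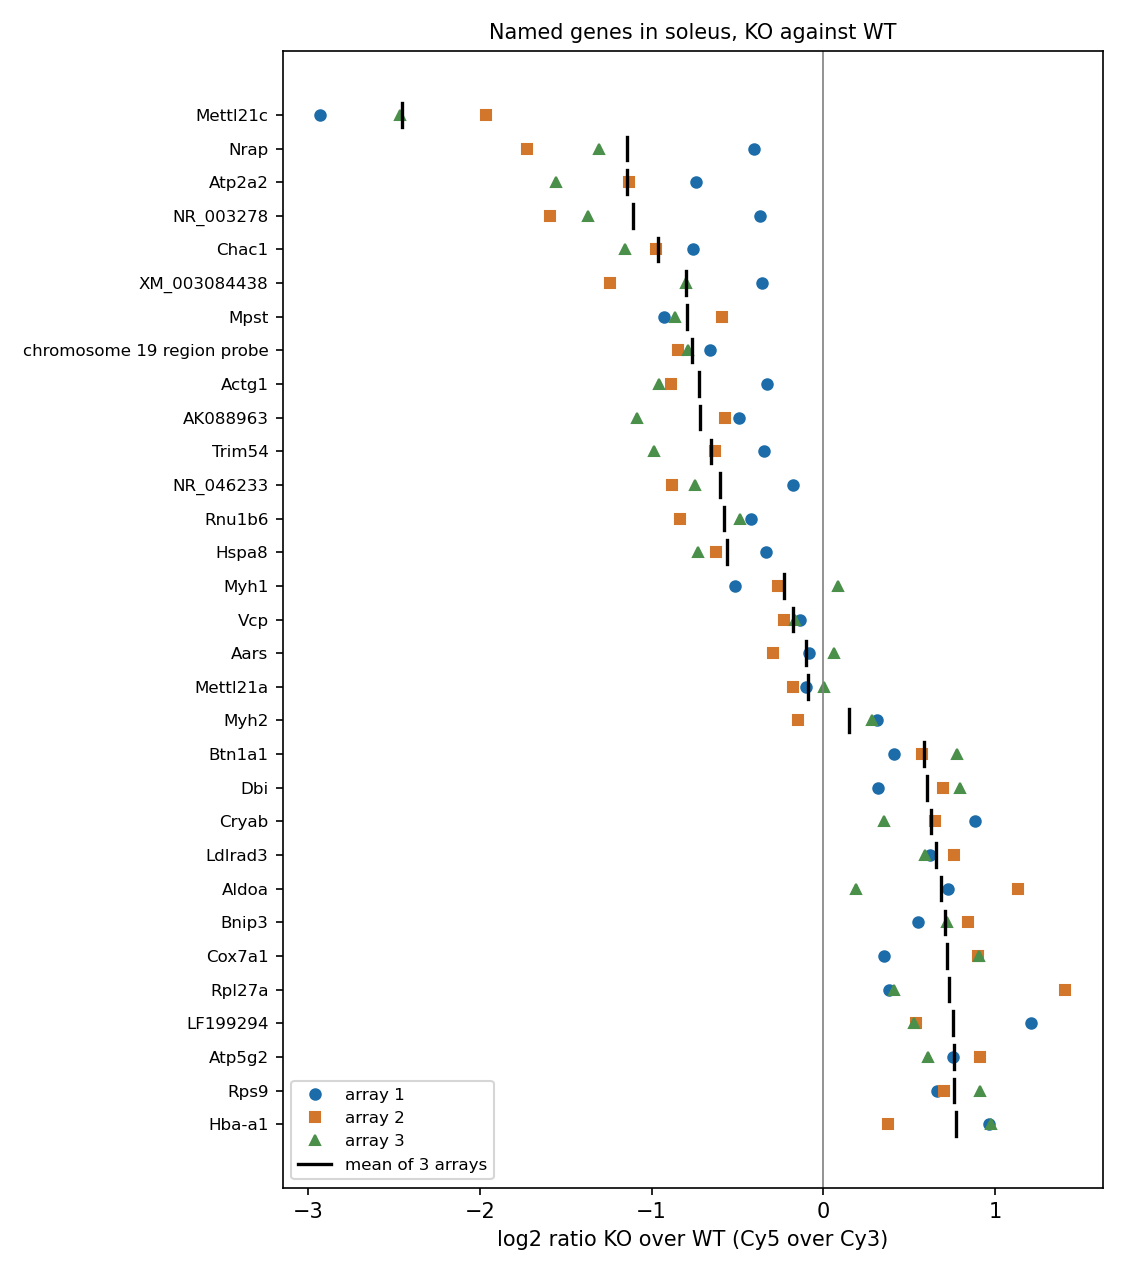
The log2 ratio of KO over WT (x axis) is shown for each named gene or transcript (y axis), with a symbol for each of the 3 arrays and a bar for their mean. Mettl21c lies lowest, with a mean of -2.45, and the highest mean is 0.77 for Hba-a1.

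The genes with the smallest p on the higher side did not pass the threshold. They were Rps9, a ribosomal protein gene, at a log2 ratio of 0.76 (SD 0.13, limma adjusted p = 0.0511), and Atp5g2, a subunit of ATP synthase, at 0.76 (SD 0.15, adjusted p = 0.0511). Ldlrad3 stood at 0.66 (SD 0.09) and Bnip3, a mitophagy receptor, at 0.70 (SD 0.15). Hba-a1, an alpha globin, was at 0.77 (SD 0.34), Cox7a1, a muscle isoform of a cytochrome c oxidase subunit, at 0.72 (SD 0.32), and Cryab, a small heat shock protein of muscle, at 0.63 (SD 0.27). Cryab was at 0.16 when spots with an outlier flag were kept, and a brighter probe of the gene, left out for lack of a value on array 3, gave 0.44 and -0.11 on arrays 1 and 2. Btn1a1 at 0.59, Dbi at 0.60, Aldoa at 0.68 with WT well above background on 2 of the 3 arrays, Rpl27a at 0.73 (SD 0.58, limma adjusted p = 0.189, and 0.40 without array 2, where it was 1.41) and the transcript listed as LF199294 at 0.76 made up the 12. All of these had a positive ratio on the 3 arrays after loess. Their average log2 intensity ran from 10.1 to 13.8, against 7.5 to 9.4 for the lower genes named below that did not pass. Direction thus went with brightness among these higher and lower genes, and an intensity trend left after loess was not tested for either side. It did not do so for every named gene, with Psme3 at 0.43 and an intensity of 7.4, and Atp2a1 at -0.65 and 9.8. With the processed signals the ratios were smaller, at 0.20 for Rps9, 0.16 for Atp5g2, 0.10 for Bnip3, 0.15 for Cox7a1, 0.13 for Cryab, 0.24 for Rpl27a, 0.32 for Ldlrad3, 0.32 for Dbi and 0.38 for LF199294, and closer for Hba-a1, at 0.73, Btn1a1, at 0.51, and Aldoa, at 0.57. When each array was centred on its median without loess, the ratio of every one of these 12 turned negative, in a setting that moved the median of all tested genes to -0.45.

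On the lower side the genes that did not pass included Mpst, a sulfurtransferase, at -0.79 (SD 0.18, limma adjusted p = 0.0511), and Atp2a2, the calcium pump of slow fibres, at -1.14 (SD 0.41, adjusted p = 0.0809). Nrap, a protein of the myotendinous junction and of myofibril assembly, stood at -1.14 (SD 0.68), Actg1, a cytoplasmic actin, at -0.72 (SD 0.35), and Trim54, a sarcomeric ubiquitin ligase, at -0.65 (SD 0.32). Rnu1b6, a spliceosomal RNA, was at -0.58. The remaining 4 carry only an accession: NR_003278 at -1.11, XM_003084438 at -0.80, AK088963 at -0.72 and NR_046233 at -0.60. With the processed signals most were larger, such as Atp2a2 at -1.49, Nrap at -1.41, NR_003278 at -1.52, Actg1 at -1.11 and AK088963 at -1.08, while Trim54 stood at -0.64, and the limma adjusted p of the 10 genes ran from 0.404 to 0.425.

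Several of these values rested on 1 probe where other probes of the gene differed. The brightest Atp2a2 probe gave -1.14 at an average log2 intensity of 8.2, and the other gave 0.09 at 6.8. For Atp5g2 the probes gave 0.76 and -0.09, at intensities of 13.3 and 7.6. For Bnip3 the brightest gave 0.70 at 13.8, while the others gave 0.08 at 7.1 and -0.01 at 6.0, the last not tested. The offset shrinks the ratios of dim probes, so small ratios there may reflect low signal. For Cox8a they gave 0.53 and -0.02. The tested probes of Actg1 gave -0.72 and -0.62, while a slightly brighter probe, left out for lack of a value on array 3, gave -0.16 and -0.11 on arrays 1 and 2. A dimmer probe of Rpl27a, left out for the same reason, gave 0.11 and -0.03 on those arrays, where the tested probe gave 0.38 and 1.41. The probes of Dbi were closer, at 0.60 and 0.43.

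**Figure D2:**
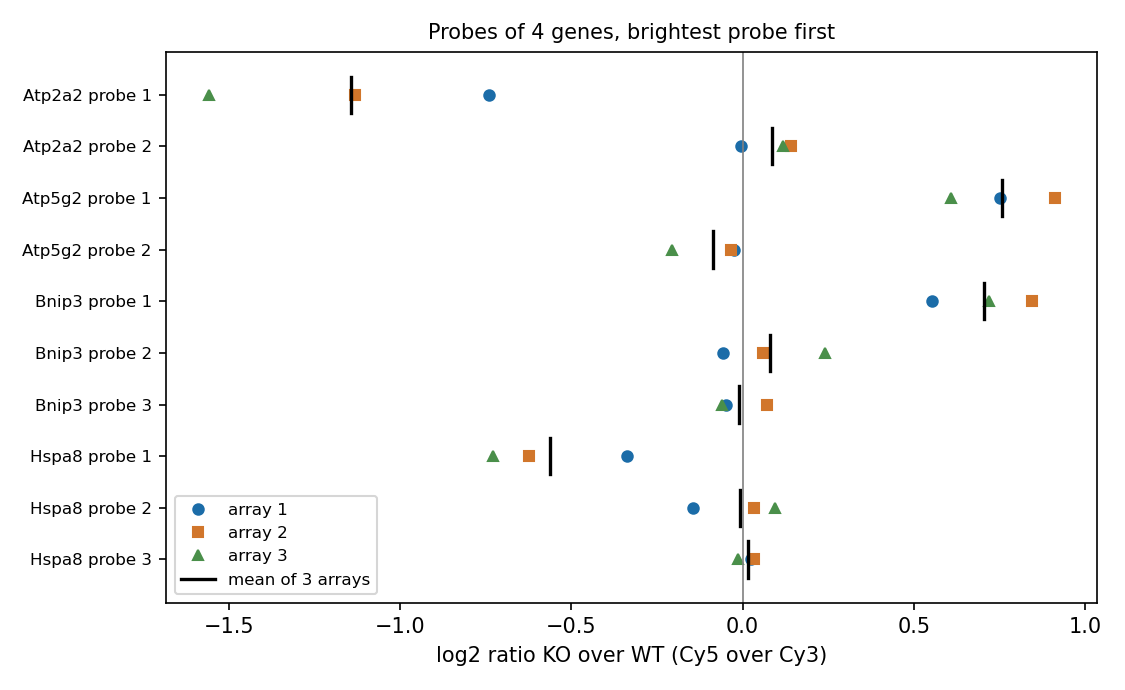
The log2 ratio of KO over WT (x axis) is shown for each probe of Atp2a2, Atp5g2, Bnip3 and Hspa8 (y axis, brightest probe first), with a symbol per array and a bar for the mean of 3 arrays. The brightest probe of Hspa8 has a mean of -0.56 and its other probes -0.01 and 0.02. These Hspa8 probes are dim, at average log2 intensities of 6.6, 6.1 and 5.9, and the last was not tested.

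Among the relatives of Mettl21c and proteins described as substrates of its family, 6 of 17 listed genes were tested. All 6 had a negative mean, though Mettl21a turned to 0.16 when arrays were centred on the tested probes without loess. The list was lower than the other genes (camera with a preset correlation, adjusted p = 1.3e-04, and adjusted p = 0.867 with an estimated correlation). Over all genes 1 member passed, Mettl21c itself, and 4 passed when adjusted over the list alone. Without Mettl21c, an alternative chosen after seeing the data, the median was -0.18 and camera gave an adjusted p of 0.0120, and an adjusted p of 0.867 with an estimated correlation. Hspa8, the constitutive HSC70 chaperone, had a log2 ratio of -0.56 (SD 0.20) at its brightest probe, while its other probes stood at -0.01 and 0.02. The Hspa8 probes were dim, at average log2 intensities of 6.6, 6.1 and 5.9, and the last was not tested. At the brightest probe the processed signals gave -1.39, and an offset of 16 gave -0.94 (limma adjusted p = 0.0169). Vcp, a hexameric ATPase, was at -0.18 (SD 0.05), Aars, the alanyl-tRNA synthetase, at -0.10 (SD 0.18), Mettl22 at -0.28 (SD 0.14) and Mettl21a at -0.09 (SD 0.09). With an array left out Aars ran from -0.19 to -0.0097 and Mettl21a from -0.14 to -0.048. In the main fit none of these 5 passed over all genes. Mettl21e was not well above background on any array in either channel.

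Genes of the fibre types were the next group, since the soleus holds many slow, oxidative fibres. Of 12 slow fibre genes tested, 9 had a positive and 3 a negative mean, with a median of 0.18 (camera adjusted p = 0.105, and adjusted p = 0.867 with an estimated correlation). None passed over all genes, and 2 higher and 1 lower passed when adjusted over the list alone. Myl3, a slow myosin light chain, was at 0.49 (SD 0.17), and at 0.060 with the processed signals, and Tnnt1, the slow troponin T, at 0.40 (SD 0.29), which was 0.25 without array 2, -0.04 with the processed signals and -0.19 (SD 0.24) at its other probe. The list's medians were 0.22, -0.04 and 0.31 on arrays 1 to 3. Without array 3 the list's median was 0.059 over the 16 genes then tested. Without array 2 its median was 0.26 (camera adjusted p = 0.0029), and with the processed signals 0.015. It passed as higher with no filter on dim probes (adjusted p = 0.0110) and with the 6 channels as samples (adjusted p = 0.0373), and as lower, with a median of -0.28, when arrays were centred on the tested probes without loess (adjusted p = 0.0443). Of 13 fast fibre genes, 6 had a positive and 7 a negative mean, with a median of -0.09 (camera adjusted p = 0.696, and adjusted p = 0.867 with an estimated correlation). Adjusted over the list alone, 1 higher and 2 lower passed. Eya1, a regulator of fast fibre genes, was at 0.53 (SD 0.03), Mylpf at -0.46 (SD 0.27) and Atp2a1 at -0.65 (SD 0.45), or -0.39 without array 3. Centred on the tested probes without loess the fast fibre list passed as lower, with a median of -0.58 (camera adjusted p = 1.6e-04). Of the myosin heavy chains, Myh1 was at -0.23 (SD 0.30), or -0.39 without array 3 and -0.089 without array 1. Myh2 was at 0.15 (SD 0.26), or 0.30 without array 2, 0.066 without array 1 and 0.082 without array 3. Myh7, the slow heavy chain, and Myh4, the type IIB heavy chain, each had an outlier flag on array 3 and were not tested. Myh7 gave 0.52 and 0.10 on arrays 1 and 2 after loess, where the scanner's log2 ratios were 0.16 and -0.33, and Myh4 gave -1.18 and 0.73.

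Of the 26 lists, 25 had at least 3 tested genes, and 4 passed in camera with the preset correlation, 2 higher and 2 lower. With an estimated correlation 0 of these 4 held, with 0 lists at an unadjusted p under 0.05, and directional fry passed 0, with 1 at an unadjusted p under 0.05. Its mixed test, which asks whether members change in either direction, passed 11. Turning the sign of 1 array gave 2, 6 or 5 lists, against 4 with the real signs.

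Oxidative phosphorylation subunits were higher than the other genes, with 40 of 66 positive and a median of 0.06 (camera adjusted p = 0.0120, and adjusted p = 0.867 with an estimated correlation). Their medians were -0.02, 0.04 and 0.13 on arrays 1 to 3, and without array 3 the median of the same 66 genes was -0.0052. None passed over all genes, and 10 higher and 0 lower passed when adjusted over the list alone. Cox8a was at 0.53 (SD 0.17), and at 0.048 with the processed signals. The list's median turned to -0.75 when arrays were centred without loess, which moved the median of all tested genes to -0.45. It turned to -0.31 when they were centred on the tested probes, which left that of all genes at -0.01. The list passed as lower in each of these settings, at a camera adjusted p of 4.1e-05 and 1.5e-06. With the processed signals its adjusted p was 0.532.

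Markers of other cell types were tested in the same way. The 7 macrophage and leukocyte markers tested all had a negative mean, with a median of -0.23 (camera adjusted p = 0.0120, and adjusted p = 0.867 with an estimated correlation). Their medians were -0.24, -0.22 and 0.06 on arrays 1 to 3. Cd74, the MHC class II invariant chain, was at -0.40 (SD 0.20), and the complement genes C1qa and C1qb were at -0.23 (SD 0.02) and -0.25 (SD 0.36), the latter -0.45 without array 3 and -0.12 without array 2. The 4 red blood cell markers tested all had a positive mean, with a median of 0.18 (camera adjusted p = 0.0188, and adjusted p = 0.867 with an estimated correlation), led by Hba-a1. Alas2, of haem synthesis, was at 0.21 (SD 0.13) and Hbb-b1, a beta globin, at 0.15 (SD 0.33), which was 0.34 without array 2, 0.033 without array 1 and 0.074 without array 3. Without array 1 neither marker list passed, each with a camera adjusted p of 0.210, and the macrophage median was -0.098. Without array 2 the macrophage median was -0.098 (camera adjusted p = 0.0780) and that of the red blood cell markers 0.34 (camera adjusted p = 4.3e-06). With the 6 channels as samples neither list passed, at an adjusted p of 0.235 and 0.122. None of these markers passed over all genes.

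**Figure D3:**
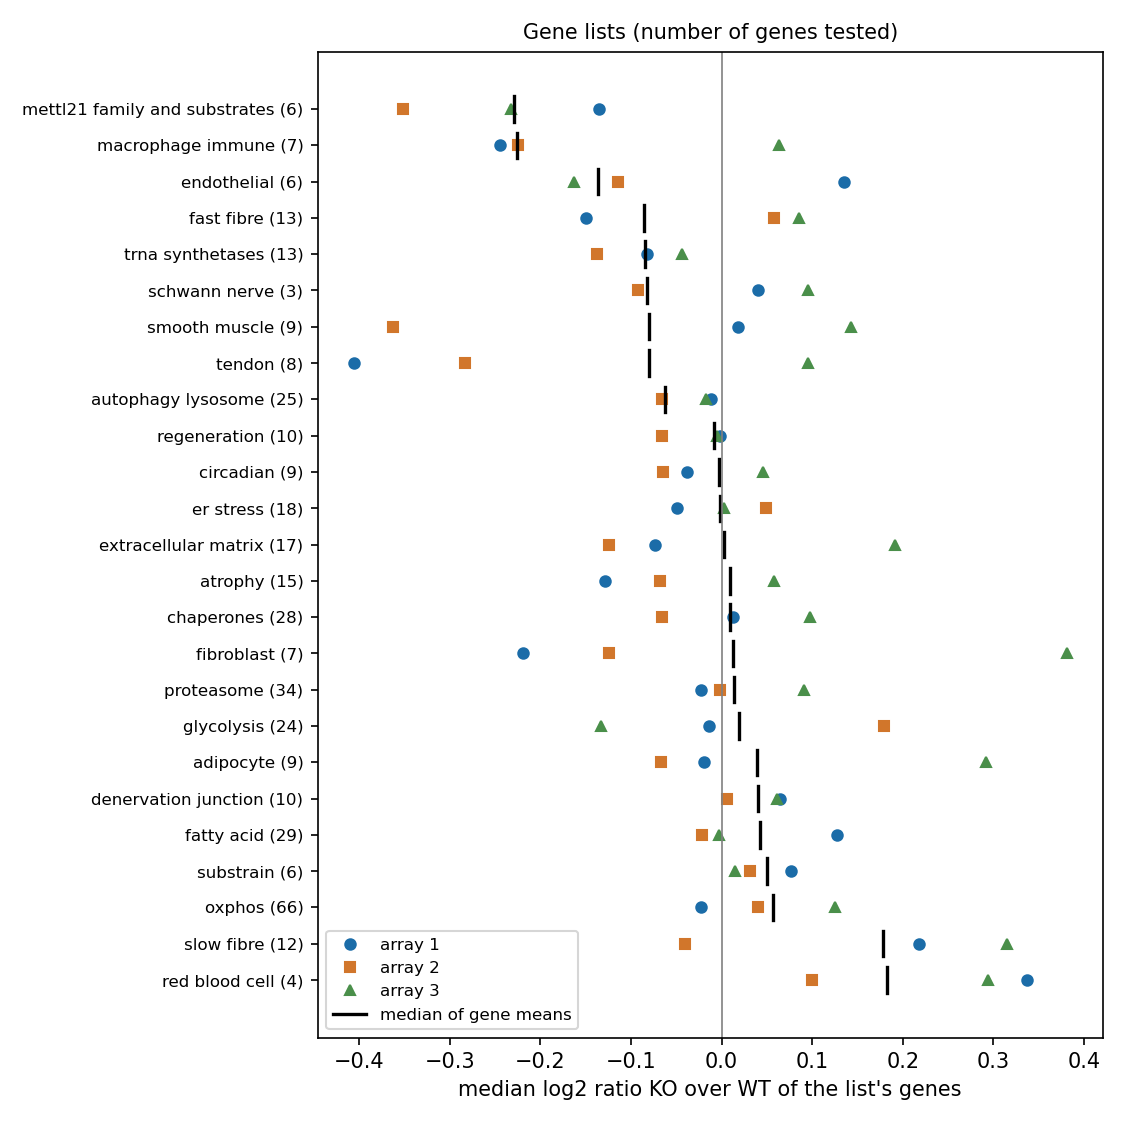
The median log2 ratio of KO over WT of each list's tested genes (x axis) is shown per array (symbols) and for the gene means (bar), with the number of genes tested beside each list name (y axis). The medians of the gene means run from -0.23 to 0.18, and several lists have arrays on both sides of 0.

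The other lists did not pass, with camera adjusted p from 0.127 to 0.857, though tendon, matrix and fatty acid genes passed without array 3, the last as higher, and fatty acid, glycolysis, chaperone, proteasome and tRNA synthetase genes passed as lower when arrays were centred on the tested probes without loess. Their medians were -0.08 for 13 tRNA synthetases, 0.04 for 29 fatty acid genes, 0.01 for 34 proteasome genes, -0.06 for 25 autophagy and lysosome genes, 0.01 for 28 chaperones, 0.04 for 10 denervation and junction genes, 0.01 for 15 atrophy genes, 0.02 for 24 glycolysis genes and -0.0030 for 9 circadian genes. They were -0.0019 for 18 endoplasmic reticulum stress genes, which hold Chac1, 0.05 for 6 genes that differ between C57BL/6 substrains, -0.0083 for 10 regeneration genes and 0.0021 for 17 matrix genes. Circadian genes turned to 0.052 without array 1, and glycolysis to -0.044 and regeneration genes to 0.078 without array 2. Without array 3 atrophy genes turned to -0.046 (18 tested), matrix to -0.083 (21), denervation to -0.0074 (15), chaperones to -0.013 (32) and stress genes to 0.013 (21). The filter was rerun with each array left out, so such medians can cover other genes. The effect of the array itself was not separated from that. The tRNA synthetase, fatty acid, proteasome, autophagy and substrain medians kept their sign with any array left out. Among cell type markers the medians were -0.08 for 8 tendon, -0.08 for 9 smooth muscle, -0.14 for 6 endothelial, -0.08 for 3 Schwann cell, 0.04 for 9 adipocyte and 0.01 for 7 fibroblast genes. Each of these 6 turned with an array left out, to 0.017 for tendon without array 1, to 0.036 for smooth muscle, 0.025 for endothelial and 0.072 for Schwann cell markers without array 2, and to -0.050 for adipocyte and -0.13 for fibroblast markers without array 3. For atrophy and matrix genes the median was positive while the mean and the direction of the test were negative. Of the neutrophil markers 1 was tested, Lcn2, at 0.04. Over all genes 1 member of these lists passed, Chac1. Adjusted over the list alone, 3 higher and 2 lower chaperones passed, 1 higher and 1 lower autophagy gene, 1 higher proteasome gene, 1 higher denervation gene, 2 lower atrophy genes and 1 lower stress gene. Examples are Hsp90ab1, a cytosolic chaperone, at 0.33 (SD 0.12), Psme3, a proteasome activator subunit, at 0.43 (SD 0.15), Hdac9, a histone deacetylase, at 0.46 (SD 0.23), and Trim63, the ubiquitin ligase MuRF1, at -0.28 (SD 0.08).

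Spike-in transcripts, which do not come from the mice, were read by 10 probes. Of a probe's spots, 3.8% to 100% were well above background in at least 1 channel. Of the 10 spike-in probes, the highest mean log2 ratio was 1.69 (SD 0.26, n = 3 arrays) and the lowest -0.53 (SD 0.24). The scanner's log2 ratios of the same probes were 2.85 (SD 0.42) and -1.16 (SD 0.56). The ratios designed for these probes are not given in the sources used here, so their departure from design was not computed.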

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

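The tests of explanations in this part were chosen only after the result was seen. Negative control spots, which carry no mouse transcript sequence and enter no comparison, gave signal in places. Of 308 such spots, 20 were well above background in the KO channel and 16 in the WT channel of array 3, and 7 in the KO channel of array 2. Each count was above the limit of 3 used for flagging, which is not a test of these counts. The brightest reached 3012 in the KO and 6006.5 in the WT channel of array 3. That array also had the most outlier flags, 1002, and the widest spread of the log2 ratio between spots of one probe, a median SD of 0.13 against 0.09 on each of the other arrays over 145 probes.

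More genes kept 1 direction on the 3 arrays than chance gives, 35.8% against 25.0%. Turning the sign of 1 array gives 4 splits with the real one, too few for a share under 0.05. The real split called 3 genes, which 1 of the 4 splits reached, and the highest other called 0. Different probes of one gene, read on different arrays, shared 0.27 of the covariance that a single probe showed (95% bootstrap interval 0.14 to 0.40, 1166 pairs in 825 genes). If no intensity trend is shared by the probes, this argues against effects of single probes as the whole cause. It equally argues against a transcript difference shared by all probes as the whole cause. The covariance was taken without removing such a trend, which probes of similar brightness could share. For the 677 pairs of similar brightness the share was 0.45 (0.28 to 0.61). A mixture may hold. A genotype effect stays open and untested, as does a dye preference shared by a gene's probes, because the dyes were never exchanged. An intensity trend repeated on the arrays also stays open.

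The oxidative phosphorylation list was higher with loess. Its median of 0.06 stood at percentile 85.9 among 10000 random lists matched on average intensity, whose central range was -0.02 to 0.08, in keeping with an intensity trend left in bright probes as a candidate explanation. The macrophage, red blood cell and slow fibre lists stood outside their matched range, at percentiles 0.02, 99.6 and 98.4. Random lists leave out the correlation between members, so these percentiles alone decide nothing. Camera with an estimated correlation gave each an adjusted p of 0.867, but it passed 0 lists and missed the shifted simulated list. Without array 3 the median of the same genes was at percentile 27.6 of matched lists, while camera on the 76 members then tested gave an adjusted p of 0.0056 with the preset correlation. The percentile and the camera result without array 3 point different ways and cover different members. Whether array 3 alone made the list higher therefore cannot be told apart. With all arrays, camera with an estimated correlation gave an adjusted p of 0.867, which for the reason above does not bear on array 3. A genotype effect stays open and untested.

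Over the gene lists, 4 passed with the real signs and up to 6 with 1 array turned, and 3 of the 4 splits gave at least as many. The 4 splits are too few for a share under 0.05.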

How the results depend on the processing

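Centring on the tested probes, keeping spots with outlier flags, testing each probe and leaving Mettl21c out of its list, with either correlation, were chosen after seeing the data. Against 3 calls, limma called 0 with the processed signals (805 of 7424 tested at an unadjusted p under 0.05) and 0 with the series matrix values (806 of 7424). It called 0 with no filter on dim probes (2468 of 36218) and 0 with both channels above background (935 of 6564). It also called 0 with the 6 channels and no replicate block (236 of 7424) and 0 with unmoderated one-sample statistics (646 of 7424). The block is the array, which pairs 1 KO with 1 WT sample. It called 5 with no background subtraction, 25 with an offset of 16, 4917 with median centring and no loess (0 higher), 2658 with centring on the tested probes (1014 higher), 1 with the mean of probes, 85 with trended and robust moderation (41 higher), 62 with array weights (45 higher), 1 at an absolute log2 ratio of at least 1, 98 at an adjusted p under 0.1 (60 higher), 1 with outlier spots kept and 1 with each probe tested, and from 0 to 16 with an array left out. The cause was not tested. With both channels required fewer genes were tested, 6564, and Mettl21c was not among them. Aquantile kept 3 calls and leaving out saturated spots changed nothing, since there were 0. A slide block was not run because all arrays lay on 1 slide.

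Mettl21c was lower under every alternative that tested it. It did not pass in limma with the processed signals (-6.23, adjusted p = 0.0680), the series matrix (-6.22, 0.0682), no filter (-2.45, 0.172), the 6 channels (-2.45, 0.752), unmoderated statistics (-2.45, 0.534) and without array 3 (-2.44, 0.0557), and the cause was not tested. Over these and the other alternatives its adjusted p ran from 1.5e-07 to 0.752, and without each array its log2 ratio ran from -2.69 to -2.21.

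Against 4 lists past the threshold, 2 higher and 2 lower, there were 2 with the processed signals, both lower, 9 with centring on the tested probes, all lower, 6 with median centring, 1 higher and 5 lower, 0 with an estimated correlation, with or without Mettl21c, 0 with directional fry and 2 to 7 with an array left out. The estimated correlation also missed the shifted list of the simulated data. For the rest the cause was not tested. The red blood cell list passed under median centring (adjusted p = 0.0258), with its own median at -0.17, and did not with centring on the tested probes (0.0584), the processed signals (0.0664), the 6 channels (0.122) or an estimated correlation (0.867). The macrophage list did not with the 6 channels (0.235) or either centring (0.527 and 0.337). Without array 3 the tendon list (median -0.36, adjusted p = 6.6e-06), matrix genes (-0.083, 0.0080) and, as higher, fatty acid genes (0.053, 0.0063) passed, where with all arrays and an estimated correlation their adjusted p ran from 0.867 to 0.951. Without array 3 these lists held 9, 21 and 33 tested genes.

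Median centring without loess moved the median of all tested genes to -0.45 and turned these log2 ratios: Rps9 -0.56, Atp5g2 -0.58, Ldlrad3 -0.41, Bnip3 -0.68, Eya1 -0.53, Btn1a1 -0.39, Cox8a -0.65, Hba-a1 -0.18, Cox7a1 -0.63, Cryab -0.47, Dbi -0.58, Myl3 -0.79, LF199294 -0.50, Aldoa -0.42, Rpl27a -0.44, Tnnt1 -0.71, Alas2 -0.051, Myh2 -0.80, Hbb-b1 -0.22, and the medians of the oxidative phosphorylation list, -0.75, and slow fibre list, -0.72. Centring on the tested probes turned Rps9 -0.12, Atp5g2 -0.14, Bnip3 -0.24, Eya1 -0.094, Cox8a -0.21, Cox7a1 -0.19, Cryab -0.032, Dbi -0.14, Myl3 -0.35, LF199294 -0.066, Rpl27a -0.0051, Tnnt1 -0.27, Myh2 -0.36, Mettl21a 0.16, the oxidative phosphorylation list, -0.31, and the slow fibre list, -0.28. Lists of glycolysis (-0.39, adjusted p = 3.0e-04), chaperone (-0.24, 0.0121), proteasome (-0.27, 0.0175) and fatty acid genes (-0.25, 0.0175) also turned there and passed as lower, and fatty acid genes passed as lower with median centring (-0.69, 0.0278). Tnnt1 was at -0.036 both with the processed signals and with the series matrix. The fast fibre list ran from -0.12 to 0.034 with an array left out, and fry gave it the other direction at its median of -0.086. It passed as lower with centring on the tested probes (median -0.58, adjusted p = 1.6e-04) and with median centring (-1.02, 0.0018). The cause of these turns was not tested. Signal over background limits dim probes, whose ratios the offset shrinks.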

Other observations

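The tests of this part were chosen after the values were seen, and so were the genes beyond the naming rule. Genes of type IIB fibres, the fastest class, differed between the pairs. Actn3, a fast fibre actinin, had log2 ratios of -1.39, 0.23 and -1.24 on arrays 1 to 3, Mybpc2 had -1.50, 0.37 and -0.95, and Pvalb, the calcium buffer of fast fibres, had -1.38, 1.11 and -0.19. The processed Myh4 signal was 1419, 1491 and 1713 in WT and 182.8, 3338 and 157.5 in KO, with an outlier flag on array 3. The brightest Pvalb probe gave 85779, 99391 and 110414 in WT and 28738, 149041 and 73391 in KO. The WT signal was higher on array 3 for other genes, with 4516, 4388 and 9159 for Actn3 against 1153, 5643 and 3147 in KO, and 5313, 5189 and 13344 for Mybpc2 against 1427, 6371 and 4816 in KO. Of 18 listed fast fibre genes 13 were tested. The glycolysis list without fast fibre genes and Gpd1 (23 genes) had a median excess of 0.21 on array 2 over the mean of the others, at percentile 100 of 10000 matched random lists. Random lists leave out the correlation between members, and array 2 was singled out after some fast fibre genes were seen to be higher there. The percentile alone therefore decides nothing. A differing amount of type IIB fibre tissue between samples, from neighbouring muscle or from the fibres themselves, stays a candidate explanation. These were not separated. The highest over the lowest processed signal was 21.2 in KO and 1.21 in WT for Myh4, 5.19 and 1.29 for the brightest Pvalb probe, 4.89 and 2.09 for Actn3, 4.46 and 2.57 for Mybpc2 and 2.05 and 1.81 for Gpd1, so for these genes the signal varied more between KO than between WT samples, though processed signals are not scaled between arrays. The whole fast fibre list was at percentile 67.7 for the same excess. It mixes fibre classes, so artefacts of single spots cannot be told apart by it. Its members tested under the naming rule, Eya1, Mylpf, Atp2a1, Myh1 and Myh2, were not highest on array 2. Mylpf had -0.15, -0.67 and -0.57 on arrays 1 to 3, and Atp2a1 -0.36, -0.42 and -1.17. The higher ratio on array 2 was thus not shared by all fast fibre genes.

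Marker lists also differed between the pairs. The fibroblast median was -0.22, -0.12 and 0.38 on arrays 1 to 3, the tendon median -0.41, -0.28 and 0.09, and the matrix median -0.07, -0.12 and 0.19.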
